A study of Mus musculus with 3 samples.

How the data were processed

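Fetal kidneys of Meis1-EGFP transgenic mice on a CD-1 background were taken at embryonic day 15.5 (Theiler stage 23), pooled in lots of about 20, and dissociated in trypsin for 5 min at 37 °C, per the labels' protocols. Meis1-EGFP mice carry a transgene in which green fluorescent protein is made under the control of the Meis1 gene. The suspension was passed through a 70 micron mesh, and cells positive for the green protein were collected by fluorescence-activated cell sorting. Total RNA was amplified in 2 rounds, labelled with biotin and hybridised to Affymetrix arrays, with 1 pool per array and 3 arrays. The labels name the sorted cells in 2 ways, as peripheral blastema in the title of the series and as nephrogenic interstitium in the source of each sample.

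The values the authors deposited are 1-colour array intensity values on a linear scale, 1 per probe set and array. The submitters' processing notes name GCOS, the scanner maker's software. Its version, the signal algorithm and the scaling target are not given in the sources used here. The mean signal after leaving out 2% of probe sets at each end was 1500.01 on every array, so the values had been scaled to a common mean before they were deposited. Signals ran from 0.07 to 66559.8, from 0.16 to 81986.5 and from 0.19 to 81080.3 in replicates 1, 2 and 3. No value was 0 or below, so log2 was taken without a pseudocount. Array scan dates were not used here.

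Each array held 45101 probe sets. Of these, 64 control probe sets were set aside, 34945 carried 1 gene symbol in the platform annotation, 932 carried several and 9160 carried none. Symbols were looked up by Entrez ID in a RefSeq gene table of assembly GRCm38.p6, which was used for names and genomic lengths only. The Entrez IDs of 34741 probe sets matched it, 204 did not, and no symbol changed. Probe sets with several symbols or none were not used for any gene. The remainder covered 18193 genes, 9010 of them with more than 1 probe set, and each gene took the value of its probe set with the highest mean log2 signal. Among genes called above background that had more than 1 probe set, 4241 of 6828 also had a probe set below the background level on at least 1 array, so many calls rest on part of a gene's probe sets.

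The series holds 1 group and therefore no contrast between groups. The question put to each gene was whether its signal lay above background. The background level of an array was the 95th percentile of the log2 signals of 72 chemosensory receptor genes (odorant, vomeronasal and trace amine receptors, which are made in sensory neurons). The log2 signal minus this level was tested above 0 with limma (lmFit with an intercept, then eBayes), one-sided, with Benjamini-Hochberg adjustment over all 18193 genes and a threshold of 0.05. A negative result does not show that a transcript was absent, since a probe set can fail, and levels of different genes were not ranked because probe sets differ in affinity.

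The tests, 28 lists of genes (cell types of the fetal kidney and its neighbours, processes and signalling pathways), a list of genes restricted to other tissues and the alternatives were fixed before the data were examined. The share of a list's measured members above background was compared with that of all other genes by Fisher's exact test, two-sided, adjusted over the 28 lists. Members were also counted with the adjustment over the list alone. The nephrogenic interstitium list was set against 8 other lists by Fisher's exact test, adjusted over the 8 pairs. Intervals of shares are exact (Clopper-Pearson) at 95%. Of 357 different list genes, 29 had no value under the rules above and were not analysed here. Genes are not independent replicates, so p-values of lists describe the genes on these arrays.

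Agreement of the arrays was described by Pearson's r and Spearman's rho across genes and by the SD over the 3 arrays after centring each on its median. For each list with 3 or more members above background, the median difference of each array from the mean of the others was set against 10000 random lists of the same size matched on mean expression in 20 bins. The log2 ratio of the 3' to the 5' control probe set of Gapdh and Actb was taken per array. The number of arrays limits the precision of every value. The labels do not say whether the pools came from separate litters, so p-values of the detection test measure only the spread between these samples, which may be technical. Each SE and p-value of that test was moderated by eBayes (prior df 3.88). They also carry the spread of the background levels (log2 7.08, 7.53 and 7.40 in replicates 1, 2 and 3), so they do not give the spread of a gene's signal alone.

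The genes named are all measured members of the nephrogenic interstitium and cap mesenchyme lists, the first 4 members above background and the first 2 not above it in each other list, and the 10 genes above background with the largest SD over the arrays. Genes outside that rule are said to be so where they appear. Alternatives were a background level at the 90th or 99th percentile, a level from the tissue-restricted genes, 1 common level, quantile normalization, a pseudocount of 32, the mean over a gene's probe sets, leaving out probe sets marked as able to cross-hybridise, leaving out the dimmest 25% of genes, a requirement to exceed the level on every array, eBayes with trend and robust settings, and each replicate left out in turn. Agreement was also computed with centring on the 75th percentile, with no centring and over all genes. The list medians were also computed over all members.

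The detection script was tested on simulated data with the real background levels and 18193 genes. Of 50 genes each placed 0.5, 1, 2 and 3 log2 units above background, 46%, 86%, 98% and 100% were called, and 4.25% of 2000 genes placed at the level were called. For the medians per array, 100% of lists of 10 genes raised by 0.3 log2 units in 1 array fell outside the central 95% of random lists, against 2% of medians of lists not raised. Analyses used R 4.3.3 with limma 3.58.1 and matrixStats 1.5.0, and figures were drawn with matplotlib 3.10.9.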

Results

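RNA was profiled in cells that carried the Meis1-EGFP reporter, sorted from E15.5 mouse kidneys. There were 3 arrays of 1 group, each from a pool of about 20 kidneys. The series set out to define the expression profile of a sorted element of the developing kidney, so the values below describe which genes and cell type programmes this population showed. Median signals were 143, 162 and 187 in replicates 1, 2 and 3, and the background levels were signals of 135, 185 and 168.

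The sorted cells had 10432 of 18193 genes (57.3%) above background, and 7761 were not above it. Of 63 genes restricted to other tissues, 6 were above background (9.52%, Fisher's exact p = 2.48e-15 against all other genes). The lowest distance that was called was 0.49 log2 units.

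Genes of the nephrogenic interstitium, the stroma of the outer kidney, were above background in 14 of 15 cases (93.3%, 95% interval 68.1% to 99.8%; 14 adjusted over the list alone). Foxd1, the transcription factor that marks cortical stromal progenitors, had a mean signal of 28706 and lay 7.47 ± 0.21 log2 units above background (SE, n = 3; 177-fold; limma adjusted p = 7.78e-07). Meis1, whose control elements drive the reporter, had a mean signal of 18486 ± 207 (SD, n = 3) and lay 6.84 ± 0.21 log2 units above background (SE), and its relative Meis2 lay 7.60 ± 0.20 above. Meis1 is counted among the 14 and in the tests of this list, although sorting on the reporter favours its detection. The share without it was not computed. Fat4, an atypical cadherin of the stroma, lay 7.59 ± 0.20 above background, and Aldh1a2, which makes retinoic acid, 7.33 ± 0.22.

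Other members followed. The Wnt antagonist Sfrp1 lay 6.81 ± 0.20 log2 units above background (SE, n = 3 here and below), the nuclear receptors Nr2f2 and Nr2f1 6.79 ± 0.22 and 5.29 ± 0.20, and the guidance factor Ntn1 6.48 ± 0.20. The retinoic acid receptor Rarb lay 5.22 ± 0.23 above, the stromal transcription factor Tcf21 4.31 ± 0.26, the proteoglycan Dcn 3.48 ± 0.24 and Dlk1 2.91 ± 0.31. Fgf7, a mesenchymal growth factor, lay 0.92 ± 0.23 above (limma adjusted p = 0.00701), a call that was lost without replicate 3 (0.77, adjusted p = 0.0899). It was also lost at the 99th percentile of the background genes (0.44), with a level from the tissue-restricted genes (0.06) and with the mean over probe sets (0.20). Rara, a second retinoic acid receptor, was the member not above background at -0.43 ± 0.23. The share of the list was higher than that of all other genes (Fisher's exact adjusted p = 0.0139). The call was lost when the dimmest genes were left out, which raises the share of all other genes (93.3%, adjusted p = 0.440).

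The cap mesenchyme, the nephron progenitors that surround the ureteric tips, showed 9 of 15 members above background (60%, interval 32.3% to 83.7%; 9 adjusted over the list alone). Gdnf, the ligand that drives ureteric branching, had a mean signal of 26804 and lay 7.37 ± 0.20 log2 units above background. The zinc finger factor Sall1 lay 6.12 ± 0.21 above, the integrin Itga8 5.47 ± 0.24, the transcription factor Wt1 4.68 ± 0.28 and Eya1 3.47 ± 0.27. Six2, which maintains nephron progenitors, had a mean signal of 591 and lay 1.86 ± 0.21 above (limma adjusted p = 0.000139), Meox1 2.59 ± 0.22, Hoxa11 1.74 ± 0.24 and Crym 1.03 ± 0.29. Cited1, a marker of the least differentiated progenitors, was not above background at -4.20 ± 0.20, and neither were Osr1 (-3.13 ± 0.37), Tmem100 (-0.71 ± 0.23), Uncx (-0.58 ± 0.29), Spock2 (-0.30 ± 0.21) and Hoxd11 (0.26 ± 0.23). The share of this list was not shown to differ from that of all other genes (Fisher's exact odds ratio 1.12, adjusted p = 1). The Eya1 value rests on 1 of 3 probe sets, and its mean over probe sets was -0.29. Crym lost its call at the 99th percentile of the background genes (0.55, limma adjusted p = 0.102).

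**Figure D1:**
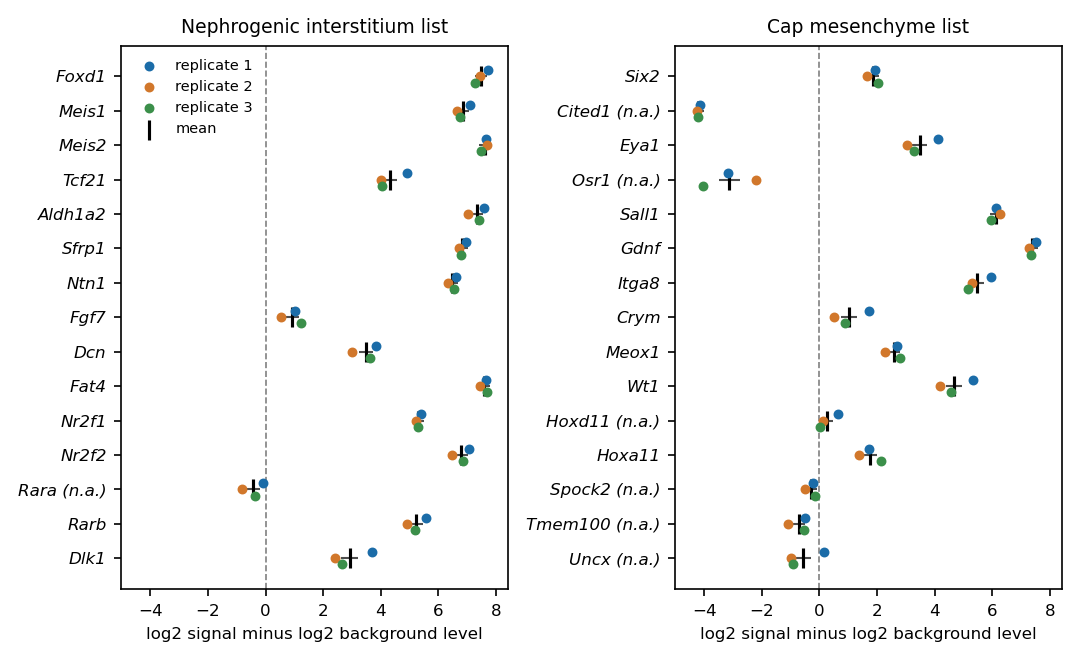
Distance of each gene from the background level of its array (log2 units, horizontal axis) for the nephrogenic interstitium and cap mesenchyme lists, with 1 coloured point per replicate, a black tick for the mean, a horizontal bar for the SE (n = 3) and a dashed line at the background level. Genes marked n.a. were not above background: Rara on the left, and Cited1, Osr1, Hoxd11, Spock2, Tmem100 and Uncx on the right.

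The labels give this sort 2 compartment names, so the interstitium list was set against cap mesenchyme and 7 other lists. Interstitium genes were above background more often than those of the ureteric bud by 62.1 percentage points (Fisher's exact adjusted p = 0.00127), the early nephron by 66.1 points (adjusted p = 0.00130) and the proximal tubule by 93.3 points (adjusted p = 2.14e-05). They also exceeded erythroid genes by 93.3 points and macrophage and leukocyte genes by 85.6 points (both Fisher's exact adjusted p = 2.14e-05), and endothelial genes by 39.5 points (adjusted p = 0.0382). Against cap mesenchyme the difference was 33.3 points and did not pass the test (Fisher's exact adjusted p = 0.0801; odds ratio 8.68, interval 0.840 to 458), nor did that against podocyte genes (43.3 points, adjusted p = 0.0602). Without probe sets able to cross-hybridise, the cap mesenchyme difference passed (36.2 points, Fisher's exact adjusted p = 0.0402). In that setting Wt1, which was above background, left the list because its only probe set is of that kind, so 8 of 14 members were above. With the mean over probe sets the podocyte difference passed (53.3 points, adjusted p = 0.0409). The endothelial call was lost in 7 of 14 alternatives, among them without replicate 3 (32.8 points, adjusted p = 0.128), and the early nephron call when the dimmest genes were left out (43.3 points, adjusted p = 0.0526).

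Among other stromal groups, all 8 genes of the medullary interstitium were above background (100%; Fisher's exact adjusted p = 0.0395), including the enkephalin precursor Penk (5.88 ± 0.31 log2 units), the ligand Wnt5a (5.06 ± 0.25), Lef1 (4.38 ± 0.25) and the Wnt inhibitor Wif1 (1.76 ± 0.20). Mesenchyme and smooth muscle of the ureter showed 7 of 10 members, with Sfrp2 at 5.45 ± 0.24 and Tbx18, a factor of ureteric mesenchyme, at 3.34 ± 0.23 and Tshz3 at 3.12 ± 0.20, while the contractile genes Tagln (-0.40 ± 0.28) and Myh11 (0.01 ± 0.20) were not above background. Mural and renin cell genes were above in 7 of 8 cases (87.5%, Fisher's exact adjusted p = 0.262), with the pericyte receptor Pdgfrb at 5.99 ± 0.23, Notch3 at 4.31 ± 0.21, Cspg4 at 4.12 ± 0.21 and Rgs5 at 2.93 ± 0.28. Des, a muscle filament gene, was not above background (0.32 ± 0.22). The medullary call was lost in 7 of 14 alternatives though all 8 genes stayed above background in them, as with quantile normalization (adjusted p = 0.0685). Rgs5 rests on 1 of 4 probe sets (mean over probe sets -0.63), and without probe sets able to cross-hybridise Notch3 lay at -0.56.

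Genes of the proximal and distal tubule and of blood cells were above background less often than other genes. Genes restricted to other tissues also had a low share (9.52%). No unsorted kidney was measured, so these calls do not show what the sort removed. None of 9 proximal tubule genes was above background (interval up to 33.6%; Fisher's exact adjusted p = 0.00261), with the phosphate transporter Slc34a1 at -0.60 ± 0.29 and the endocytic receptor Lrp2 at -0.64 ± 0.22. None of 5 distal tubule genes was (adjusted p = 0.0395), with Umod at -1.79 ± 0.26 and the cotransporter Slc12a1 at -1.10 ± 0.30. None of 10 measured erythroid genes was (Fisher's exact adjusted p = 0.00186), with the globins Hba-a1 at -2.38 ± 0.33 and Hbb-bh1 at -1.36 ± 0.22. Hba-a1 rests on 1 probe set. Another 3 of the 13 genes on the erythroid list had no value, since probe sets with several symbols or none were not used. Of 13 macrophage and leukocyte genes 1 was above background (7.69%, adjusted p = 0.00200): the receptor Csf1r, at 1.15 ± 0.20. Csf1r lost its call with the mean over probe sets (0.26) and with a level from the tissue-restricted genes (0.29). Cd68 lay at -0.57 ± 0.21 and Ptprc, the common leukocyte antigen, at -1.05 ± 0.32. The counts adjusted over each list alone were the same for these 4 lists. With only 5 genes, the distal tubule call was lost when the level was taken at the 99th percentile (adjusted p = 0.0648).

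Other cell types had some members above background and no call. Ureteric bud genes were above in 5 of 16 cases (31.2%, Fisher's exact adjusted p = 0.100; 4 adjusted over the list alone), with the adhesion protein Epcam at 4.13 ± 0.24 log2 units, Krt18 at 2.19 ± 0.22, the tip ligand Wnt11 at 2.06 ± 0.23 and Calb1 at 1.64 ± 0.28, while Ret, the Gdnf receptor, lay at -0.34 ± 0.25 and Wnt9b at -0.13 ± 0.22. Early nephron genes were above in 3 of 11 cases (27.3%, adjusted p = 0.128): Papss2 at 3.10 ± 0.25 and the Notch ligands Jag1 at 3.08 ± 0.24 and Dll1 at 1.01 ± 0.26, with Wnt4 at -0.07 ± 0.20 and Pax8 at -0.36 ± 0.26. Podocyte genes were above in 3 of 6 cases (50%, adjusted p = 0.759; 4 adjusted over the list alone), with the transcription factor Foxc2 at 4.71 ± 0.24, Synpo at 2.14 ± 0.21 and Podxl at 1.88 ± 0.22. The slit diaphragm gene Nphs1 lay at -1.66 ± 0.28 and Ptpro at -0.56 ± 0.30. Endothelial genes were above in 7 of 13 cases (53.8%, adjusted p = 0.817), with the angiopoietin receptor Tek at 2.86 ± 0.20, Cd34 at 1.47 ± 0.29, Cdh5 at 1.31 ± 0.23 and Kdr at 1.07 ± 0.21. Pecam1, an adhesion molecule of endothelial junctions, lay at -1.64 ± 0.71 and Flt1 at -0.67 ± 0.25. Neural genes were above in 3 of 8 cases (37.5%, adjusted p = 0.418), with Dbh at 2.47 ± 0.24, Elavl4 at 1.57 ± 0.25 and Stmn2 at 0.80 ± 0.22, against Sox10 at -0.20 ± 0.21 and the neuronal tubulin Tubb3 at -3.90 ± 0.29. Adrenal cortex genes were above in 2 of 7 cases (28.6%, adjusted p = 0.262; 1 adjusted over the list alone), the corticotropin receptor Mc2r at 3.26 ± 0.22 and Cyp21a1 at 0.56 ± 0.21. Nr5a1 (-0.52 ± 0.41) and Star (0.53 ± 0.27) were not above background. The mean over probe sets placed Calb1 (-1.43), Papss2 (-0.37), Cdh5 (-0.04), Stmn2 (-0.12) and Cyp21a1 (-0.52) below background and ended the calls of Synpo (0.53), Elavl4 (0.48) and Dbh (0.40; 0.0092 without probe sets able to cross-hybridise). A level from the tissue-restricted genes ended those of Dll1 (0.15), Kdr (0.21), Cd34 (0.61) and Cdh5 (0.45). Stmn2 lost its call without replicate 3 (0.67) and Cyp21a1 when replicate 1, 2 or 3 was left out (0.43, 0.63 and 0.63). Without replicate 1 the ureteric bud share was lower than that of other genes (25%, adjusted p = 0.0434). With the mean over probe sets the neural share was lower too (0%, Fisher's exact adjusted p = 0.0137).

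**Figure D2:**
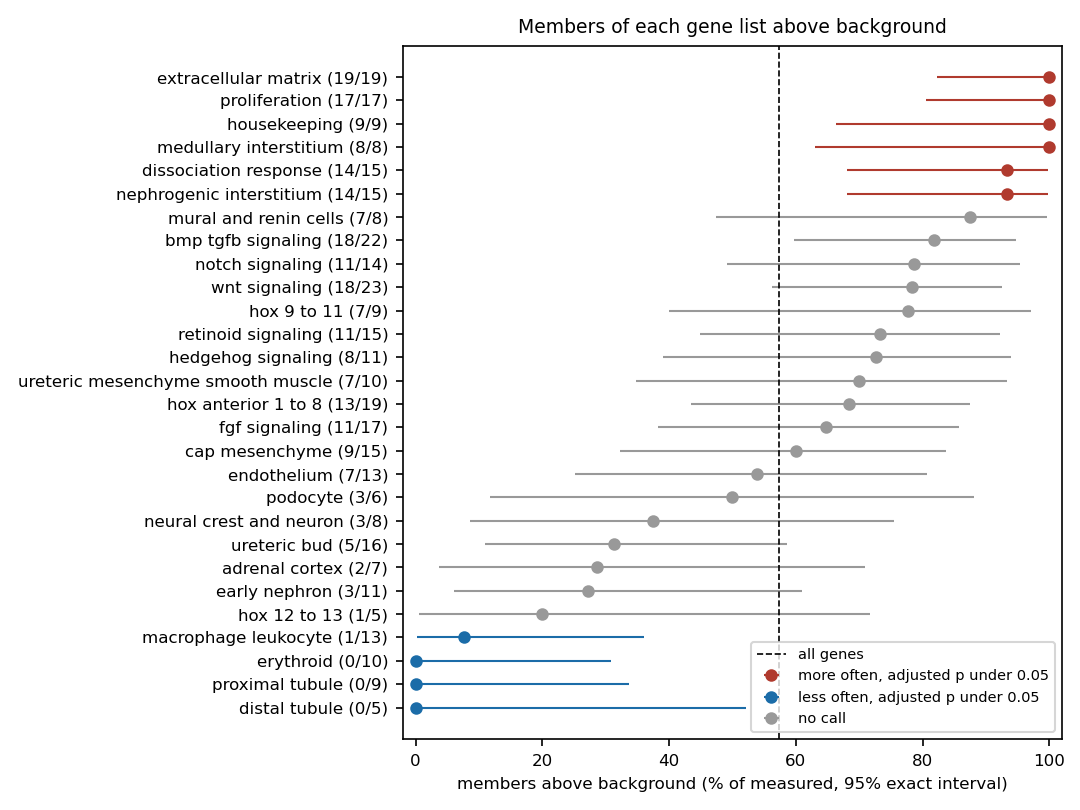
Share of each list's measured members above background (percent, horizontal axis) with exact 95% intervals, for 28 gene lists with their counts in brackets. Red points are lists above background more often and blue points less often than all other genes (Fisher's exact adjusted p under 0.05), grey points have no call, and the dashed line is the 57.3% of all genes.

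All 17 measured proliferation genes were above background (Fisher's exact adjusted p = 0.00126), with Top2a at 7.96 ± 0.21 log2 units, Mki67, the Ki-67 antigen, at 7.89 ± 0.20, Cdk1 at 6.74 ± 0.22 and Ccna2 at 6.71 ± 0.21. All 19 extracellular matrix genes were (adjusted p = 0.000785), with the fibrillar collagens Col3a1 at 8.73 ± 0.20, Col1a2 at 7.71 ± 0.23, Col1a1 at 6.33 ± 0.22 and Col5a1 at 5.94 ± 0.22. Immediate early and heat shock genes, which rise when tissue is dissociated, were above in 14 of 15 cases (93.3%, Fisher's exact adjusted p = 0.0139), with Egr1 at 7.98 ± 0.21, Fos at 7.17 ± 0.20, Jun at 4.63 ± 0.23 and Fosb at 1.04 ± 0.21, and Junb not above background at -1.66 ± 0.50. All 9 housekeeping genes were above (adjusted p = 0.0395), with Actb at 6.62 ± 0.22, Hprt at 6.15 ± 0.22, Tbp at 3.87 ± 0.25 and B2m at 3.52 ± 0.21. No undissociated kidney was measured here, so the dissociation genes have no reference level. The call of the dissociation list was lost with a level from the tissue-restricted genes (73.3%, adjusted p = 0.195), as was that of Fosb (0.18). Fosb also lost its call at the 99th percentile (0.55). The calls of all 4 lists were lost when the dimmest genes were left out (adjusted p = 0.156 for proliferation, 0.118 for matrix, 0.177 for dissociation and 0.440 for housekeeping).

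Signalling genes were above background in most cases without passing the list test. BMP and TGF-beta genes were above in 18 of 22 cases (81.8%, Fisher's exact adjusted p = 0.0728), with the receptor Bmpr1a at 7.11 ± 0.21 log2 units and the ligands Bmp5 at 3.92 ± 0.21, Bmp7 at 3.68 ± 0.24 and Bmp4 at 0.89 ± 0.22. Bmp2 (-1.10 ± 0.31) and Tgfb1 (-1.01 ± 0.21) were not above background. Wnt genes were above in 18 of 23 cases (78.3%, adjusted p = 0.120), with Wnt5b at 3.25 ± 0.26, Wnt7b at 0.61 ± 0.24 and Wnt2b not above at -0.19 ± 0.20. Retinoid genes were above in 11 of 15 cases (73.3%, adjusted p = 0.418), with Rxra at 3.91 ± 0.24 and Rarg at 2.36 ± 0.25, while the synthetic enzymes Aldh1a1 (-3.07 ± 0.60) and Aldh1a3 (0.44 ± 0.27) were not above background. Hedgehog genes were above in 8 of 11 cases (72.7%, adjusted p = 0.453): the receptor Ptch1 lay at 7.31 ± 0.21, Smo at 6.13 ± 0.24, Gli2 at 6.11 ± 0.21 and Gli1 at 2.19 ± 0.22, while the ligands Shh (-1.10 ± 0.24) and Ihh (-0.04 ± 0.21) were not above background. Notch genes were above in 11 of 14 cases (78.6%, adjusted p = 0.271), with Notch2 at 5.41 ± 0.24, Notch1 at 4.83 ± 0.21 and Notch4 at 0.59 ± 0.24, and Hey2 (0.41 ± 0.21) and Dll4 (-0.15 ± 0.22) not above background. FGF genes were above in 11 of 17 cases (64.7%, adjusted p = 0.705), with the receptors Fgfr2 at 4.56 ± 0.21, Fgfr1 at 3.68 ± 0.22 and Fgfr3 at 2.89 ± 0.23 and the ligands Fgf2 at -1.17 ± 0.23 and Fgf8 at -4.84 ± 0.22. The BMP and TGF-beta list passed without replicate 1, 2 or 3 (Fisher's exact adjusted p = 0.0424, 0.0466 and 0.0351). Its own share stayed at 81.8% each time, while the share of all genes above background was 56.1%, 57.1% and 54.7%, against 57.3% with all arrays. The Notch list passed (92.9%) with the level at the 90th percentile (adjusted p = 0.0384), with a common level (0.0362) and with the requirement to exceed the level on every array (0.0361). The mean over probe sets placed Rarg (-0.68), Bmp7 (-0.23), Wnt7b (-0.07) and Notch4 (-0.23) below background. Bmp4 lost its call at the 99th percentile of the background genes (0.41). Fgfr2 lay at -0.38 without probe sets able to cross-hybridise. Wnt7b lost its call without replicate 1, 2 or 3 (0.54, 0.44 and 0.84), and Notch4 without replicate 1 or 3 (0.44 and 0.53).

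Hox genes, which encode position along the body axis, were above background in 13 of 19 cases for paralogue groups 1 to 8 (68.4%, Fisher's exact adjusted p = 0.453), in 7 of 9 for groups 9 to 11 (77.8%, adjusted p = 0.423) and in 1 of 5 for groups 12 and 13 (20.0%, adjusted p = 0.271; 0 adjusted over the list alone). Hoxa9 lay at 7.49 ± 0.20 log2 units, Hoxa5 at 6.23 ± 0.21, Hoxa10 at 6.01 ± 0.25, Hoxb2 at 3.04 ± 0.21, Hoxa3 at 2.21 ± 0.24, Hoxa2 at 1.56 ± 0.20 and Hoxc9 at 1.11 ± 0.22. Hoxa7 (-2.60 ± 0.35), Hoxa4 (-1.57 ± 0.39), Hoxb9 (-0.47 ± 0.37), Hoxa13 (-0.72 ± 0.27) and Hoxb13 (-5.33 ± 0.30) were not above background. The called member of groups 12 and 13 was Hoxd13, at 0.78 ± 0.29, which lost its call without replicate 1 (0.43), where the share of that list became lower than that of other genes (0%, Fisher's exact adjusted p = 0.0424). The mean over probe sets of Hoxd13 was -1.60, and Hoxc9 lost its call at the 99th percentile of the background genes (0.62).

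Across the 10432 genes above background, Pearson's r between arrays was 0.986 to 0.989 and Spearman's rho 0.988 to 0.989 (correlations across genes, which are not independent replicates). The median SD over the arrays was 0.163 log2 units, the median coefficient of variation was 11.4%, and 205 genes (1.97%) differed by more than 2-fold between their highest and lowest array. Over all 18193 genes, which include those near or below background, the median SD was 0.244 and 4372 genes (24.03%) differed by more than 2-fold. With the mean over probe sets, 764 of the genes then called did. Genes with a small SD pass the detection test more easily. However, the requirement to exceed the level on every array, which does not use the SD, shared 10429 of the 10432 calls. Spry4, an inhibitor of FGF signalling, had the largest SD, with signals of 2791, 2182 and 510 in replicates 1, 2 and 3. Of its other probe sets over the level, 1 gave 411, 436 and 250 and another 563, 655 and 585. Kcnq1ot1, an imprinted long non-coding RNA, gave 2048, 4206 and 7575, the kinase gene Nrk 628, 839 and 1946, and Znhit1 3885, 2144 and 1155. The other genes with the largest SD were Pmf1, 4930444G20Rik, Uty, Cdc14a, Gm38983 and Scml2. Without replicate 1, 50 genes differed by more than 2-fold between the remaining pair, without replicate 2 it was 101 and without replicate 3 it was 95. Pmf1 and Gm38983 lost their calls without replicate 1 (0.86 and 0.44).

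**Figure D3:**
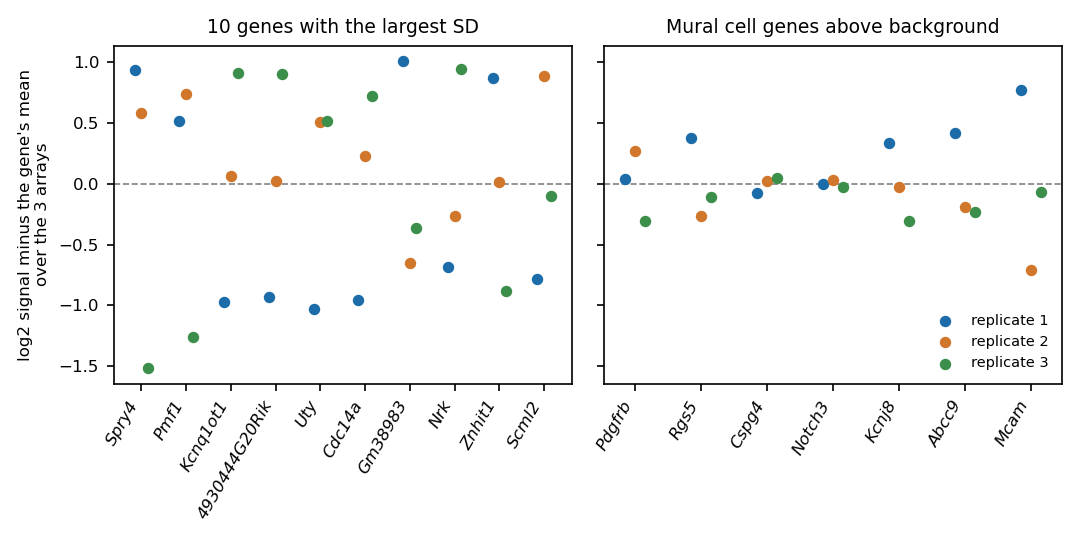
Log2 signal minus the mean of that gene over the 3 arrays (vertical axis) for the 10 genes above background with the largest SD and for the 7 mural cell genes above background, with 1 coloured point per replicate and a dashed line at the gene's own mean. Of the mural genes, 5 of 7 were higher in replicate 1 than the mean of the others after centring.

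Some gene groups varied together between pools. The 7 mural and renin cell genes had a median 0.47 log2 units higher in replicate 1 than the mean of the other arrays, above all random lists matched on expression (percentile 100; 5 of 7 genes higher), and Rgs5 was higher there by 0.54. The 8 medullary interstitium genes were higher in replicate 1 by a median of 0.27 (percentile 99.01; 5 of 8 genes) and had a median of -0.25 in replicate 2 (percentile 0.53; 2 of 8 higher). Medians in replicate 2 were -0.47 for the 3 early nephron genes (percentile 1.14; 0 of 3 higher) and -0.33 for the 5 ureteric bud genes (percentile 1.16; 1 of 5 higher), and in replicate 3 it was 0.29 for the 7 endothelial genes (percentile 97.8; 5 of 7 higher). Of 66 medians over 22 lists, 13 fell outside the central 95% of random lists, where 3.3 would for lists of unrelated genes. Members of a real list can vary together, some genes are on more than 1 list, and a list's medians on the 3 arrays are tied. The excess therefore does not measure a departure from chance. With quantile normalization 7 did, and with the mean over probe sets 3 did. Of the 13, 6 were low values in replicate 2. That array also had the highest mean log2 ratio of 3' to 5' control probe sets (4.39, against 4.02 and 4.15) and the fewest genes over its level (11091, against 11716 and 11563). Its level was itself the highest (signal 185, against 135 and 168), which lowers that count. With the mean over probe sets, the medians for medullary interstitium (0.13 in replicate 1, -0.15 in replicate 2), early nephron (-0.05), ureteric bud (-0.31) and endothelium (0.11) came within the central 95%. So did medullary interstitium in replicate 1 with quantile normalization (0.09) and endothelium over all members (percentile 93.3).

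Control transcripts showed more signal at their 3' ends on every array. The log2 ratio of the 3' to the 5' probe set was 5.22 ± 0.20 (SD, n = 3) for Gapdh and 3.16 ± 0.21 for Actb. The mean of both was 4.02, 4.39 and 4.15 in replicates 1, 2 and 3.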

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

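All tests in this part were planned. The number of genes above background lay between 9166 and 10999 over the alternatives, and between 9951 and 10385 with a replicate left out. Of 106 named genes above background, 74 stayed so in every alternative and 32 lost the call in 1 or more, and of 47 not above it, 42 stayed so and 5 gained the call in 1 or more (Aldh1a3, Des, Hey2, Hoxd11 and Star). Genes close to the background level cannot be placed firmly on either side: in simulated data 46% of genes 0.5 log2 units above it were called. No paired analysis was possible because the series holds 1 group. The cause of the changes below was not tested unless one is given.

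The interstitium exceeded ureteric bud, proximal tubule, erythroid and macrophage genes past the threshold in all 14 alternatives. Against endothelium the call was lost at the 90th (24.1 points, adjusted p = 0.184) and 99th percentile (40.5), with a common level or a requirement to exceed the level on every array (31.8 in both), with the mean over probe sets (32.8), without the dimmest genes (23.3) and without replicate 3, where leaving out a replicate gave 32.8 to 39.5 points and adjusted p over all alternatives ran from 0.00744 to 0.305. The early nephron difference fell to 43.3 points without the dimmest genes (adjusted p 0.00130 to 0.0526 over alternatives). The podocyte difference passed with the mean over probe sets (53.3 points, Fisher's exact adjusted p 0.0409 to 0.447 over alternatives). That against cap mesenchyme passed without probe sets able to cross-hybridise (36.2 points, 0.0402 to 0.215), where Wt1 left the list.

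Leaving out the dimmest genes left 0 lists above background more often, since it raises the share of all genes above background: interstitium (93.3%) and medullary interstitium, proliferation, dissociation, matrix and housekeeping (each 100%) lost the call, as did distal tubule (0%), while ureteric bud gained one (38.5%). The medullary call (100% each time) was also lost at the 90th percentile, with quantile normalization, a common level, the pseudocount of 32, the requirement on every array, and trend and robust eBayes. Distal tubule (0%) lost its call at the 99th percentile, with tissue-restricted background genes and with the mean over probe sets, and the dissociation list at the 99th percentile (80%) and with tissue-restricted background genes (73.3%). The Notch list gained a call at the 90th percentile, a common level and the requirement on every array (92.9% each), the neural list with the mean over probe sets (0%), and the BMP and TGF-beta list without probe sets able to cross-hybridise (81.8%) and with each replicate left out (81.8% to 81.8%). With a replicate left out, ureteric bud gave 25% to 31.2% and Hox groups 12 and 13 0% to 20.0%, both with a call without replicate 1.

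Tissue-restricted background genes turned Stmn2 (-0.061), Cyp21a1 (-0.30), Wnt7b (-0.25), Notch4 (-0.27) and Hoxd13 (-0.077) below the level. The mean over probe sets did so for Eya1 (-0.29), Papss2 (-0.37), Calb1 (-1.43), Cdh5 (-0.040), Rgs5 (-0.63), Stmn2 (-0.12), Cyp21a1 (-0.52), Rarg (-0.68), Wnt7b (-0.073), Bmp7 (-0.23), Notch4 (-0.23), Hoxd13 (-1.60), Pmf1 (-0.73) and Uty (-0.97). Leaving out probe sets able to cross-hybridise did so for Notch3 (-0.56), Fgfr2 (-0.38) and Pmf1 (-3.11). In these genes the probe sets disagree.

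Over all genes the median SD was 0.244, the lowest r 0.968 and 4372 genes exceeded 2-fold. With the mean over probe sets these were 0.213, 0.976 and 764, and with a replicate left out 0.124 to 0.139, 0.986 to 0.989 and 50 to 101, a pair having a smaller range than 3 arrays. Medians outside the central 95% numbered 7 with quantile normalization and 3 with the mean over probe sets. The mural median in replicate 1 stayed outside in all 5 alternatives (0.27 to 0.55). Signs turned for interstitium in replicate 2 (0.0392 with the mean over probe sets, 0.0613 without probe sets able to cross-hybridise), Wnt in replicate 3 (-0.0418 with the mean over probe sets), Hox groups 1 to 8 in replicate 1 (0.0204 with the mean over probe sets, 0.0025 over all members) and Hox groups 9 to 11 in replicate 1 (0.0403 over all members). The 3' to 5' ratio was 5.22 with Gapdh only and 3.16 with Actb only.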

Other observations

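All tests of explanations in this part were chosen after the results were seen, and genes named here but not in the report were chosen after their values were seen.

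Members of the same list lay on different sides of background. Epcam lay 4.13 ± 0.24 log2 units above background (SE, n = 3) with both of its probe sets, while the epithelial genes Cdh1 (-0.79), Krt8 (-0.25), Krt19 (-3.13) and Cdh16 (-0.64) were not above it. Krt18 (2.19), Wnt11 (2.06) and Calb1 (1.64) of the same list were above it. Mc2r lay 3.26 ± 0.22 above, while Nr5a1 (-0.52 ± 0.41), which adrenal cortex cells express, was not. The pools disagreed on Nr5a1, which lay at -1.60, -0.48 and 0.52 in replicates 1, 2 and 3 and so exceeded the level in replicate 3. Of the genes restricted to other tissues, Krt10 (3.06), Ighm (2.26), Lor (1.89), Prm1 (0.63), Apoa2 (0.55) and Pomc (0.55) were above background. Signals of the Y-linked genes Eif2s3y (1599, 3861 and 3532), Uty (202, 587 and 591) and Kdm5d (238, 641 and 411) in replicates 1, 2 and 3 differed between pools. Xist, counted below among nuclear RNAs, gave 10894.5, 8492 and 18943 with its brightest probe set. That probe set was highest in replicate 3, not in replicate 1 where these Y-linked signals were lowest. The other Xist probe sets gave 5852, 3835 and 7384, and 332, 173 and 237. Each Xist probe set was higher in replicate 1 than in replicate 2, the reverse of the Y-linked genes. Whether the pools differed in sex was not tested.

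Gdnf, Sall1, Itga8 and Wt1 lay far above background while Cited1 and Osr1 did not, although all are on the cap mesenchyme list. Cap mesenchyme cells in the sorted population may be the cause: of 8 genes more restricted to nephron progenitors, 3 were above background (Six2, Crym and Meox1), and 2 at the 99th percentile, where Crym lost its call. What these counts would be with or without such cells was not measured, so they cannot decide it. For comparison, 57.3% of all genes and 9.52% of the tissue-restricted genes were above background. Cited1 and Osr1 each have only 1 probe set, so this stays open. The design, with 1 group, names no biological difference to test.

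Nuclear long non-coding RNAs were higher in replicate 3: all 9 with a probe set over the level by the mean of replicates 1 and 2 (Malat1, Meg3, Xist, Neat1, Airn, Rian, Kcnq1ot1, Miat and Mirg) exceeded the mean of the other arrays. The median over genes was 0.30 log2 units with the brightest probe set of each and 0.66 with the median over its probe sets. Higher there were also all 27 such probe sets and 41 of the 43 probe sets of the 10 genes examined, all after centring each array on its median. The rise was not uniform, and some of the 27 lay close to 0, such as Meg3 probe sets at 0.0082 and 0.011 and a Xist probe set at 0.0045. The deposited signals of the Meg3 probe set at 0.0082 were 1929, 1917 and 1908 in replicates 1, 2 and 3. The 2 medians compare with a median of -0.00076 for 5 spliced hosts of small nucleolar RNAs such as Gas5. Scaling by the authors is argued against, since after quantile normalization the 2 medians were 0.25 and 0.707 (25 of 27 probe sets higher). The mean 3' to 5' ratio of replicate 3 differed by -0.0568 from the other arrays and lay within their range. It cannot decide on RNA fragmentation, since the SD over the arrays was 0.19 and only Gapdh and Actb were measured. For Actb alone, replicate 3 lay lowest (3.036, against 3.038 and 3.403 in replicates 1 and 2). More nuclear or non-polyadenylated RNA in the material of replicate 3 may account for the higher values of these RNAs: the deviation of replicate 3 rose with genomic length across 10405 genes (Spearman's rho 0.127; highest of 1000 permutations 0.0294), and all 3 18S rRNA probe sets were higher (median 1.27). The trend is small, with a median of 0.0163 in the longest 25% of genes and -0.0633 in the shortest 25%. Replicate 1 shows the opposite one (rho -0.127), so this trend does not separate an excess in replicate 3 from a deficit in replicate 1. With the median over probe sets, the nuclear RNAs had a median over genes of -0.28 in replicate 1. A rise in replicate 3 alone would also lower that value, since replicate 3 is in the mean of the others. The 18S signals were alike in replicates 1 and 2 and higher in replicate 3 (3324, 3940 and 8751 for the 3' probe set, 18772, 18448 and 38299 for the middle 1, 1481, 1595 and 4256 for the 5' probe set). These 18S values bear on non-polyadenylated RNA and do not show an excess of nuclear RNA. For Malat1, 1 probe set gave 1604, 2533 and 13554 and another 5958, 7816 and 7160, and no biological explanation was tested.

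Mural cell genes were higher in replicate 1, with differences from the other arrays of 1.14 for Mcam, 0.61 for Abcc9, 0.54 for Rgs5 and 0.47 for Kcnj8. Scaling that depends on signal is argued against, since the list's median after quantile normalization was 0.306 and still outside the central 95% of random lists. A larger share of mural cells in that pool may contribute. The number of genes higher was 5 of 7, with Cspg4 (-0.14) and Notch3 (-0.04) lower and Pdgfrb at 0.03, but it was 7 of 7 with the mean over probe sets, 6 of 7 without probe sets able to cross-hybridise and 4 of 7 after quantile normalization. Pdgfrb, Cspg4 and Notch3 can also come from other stromal cells, which keeps the question open.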
